A study of Homo sapiens with 4 samples.

How the data were processed

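Total RNA of NUGC3, an established human gastric cancer cell line, was measured on 4 single-colour Affymetrix expression arrays, 2 of cells described as PRMT6 wild type (control) and 2 of PRMT6 knockout cells. Per the labels, the knockout used a lentiviral Cas9 vector with a guide against PRMT6, puromycin selection and limiting dilution to clones. How many clones the knockout arrays hold, and whether the control cells carried a vector, is not given in the sources used here. The labels call the arrays replicates 1 and 2 of each group, and nothing in them says whether these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

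The deposited values are log2 expression per probe set, made by the authors with RMA and the affy package per the submitters' processing notes; the versions and the background and summarisation settings are not given in the sources used here. By its usual definition RMA corrects the background of each array, forces a common distribution on the probe intensities and summarises the probes of a probe set, so a change shared by most transcripts would be removed, and probe sets close to the background have compressed fold changes. The medians of the arrays lay at 4.73 and 4.77 for control replicates 1 and 2 and at 4.75 and 4.73 for knockout replicates 1 and 2, and all values lay between 1.36 and 14.0. The distributions were not identical: the upper quartile was 6.62 on control replicate 2, against 6.79 on control replicate 1 and 6.77 and 6.78 on knockout replicates 1 and 2. Arrays have no read depth, and their number limits the precision.

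The table held 54613 probe sets, all of which had a value on each array. The platform annotation gave 1 gene symbol for 41091 of them, several for 1801 and none for 11721. Symbols were matched by gene ID to the reference gene table of assembly GRCh38.p14 for 41037 probe sets, which changed 0 symbols. That table was used for names and for the order of genes along chromosomes, and no coordinates were taken from it. Each of 19775 genes was represented by the probe set with the highest mean over the 4 arrays, among probe sets with 1 symbol. Some genes are not reported here.

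Knockout and control were compared with limma (version 3.58.1, in R 4.3.3), using lmFit and eBayes with default settings on the deposited log2 values, the group as the only term, a two-sided test and Benjamini-Hochberg adjustment over all genes. A gene was called changed at an adjusted p under 0.05. Fold changes are knockout over control, and SE is the moderated standard error. With 2 arrays against 2, the smallest two-sided p that an exact permutation test can give is 0.333, so the calls rest on limma's model, which pools the spread of a gene with that of the others (prior degrees of freedom 2.48).

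The genes named were fixed by a rule before the data were examined: PRMT6; among changed genes whose knockout values both lay above or both below the control values, the 12 with the highest and the 12 with the lowest log2 fold change (all that passed, if fewer; if under 5 passed in all, the 8 with the smallest p in each direction); the up to 4 members with the smallest p of each gene list; and PCDH7, SCD, IGFBP5, CDKN1A, CDKN1B, CDKN2A and THBS1 whatever their values. PCDH7, SCD and IGFBP5 were recalled as genes the study followed up, so they are not independent of these samples. The others of this group have been reported elsewhere as PRMT6 targets.

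Also fixed before the data were examined were 35 gene lists: protein arginine methyltransferases; genes reported elsewhere as repressed by PRMT6; HOX genes; H3K4 methyltransferase complexes; replication and G1/S; G2/M and mitosis; genes induced by DNA damage; epithelial adhesion and keratins; mesenchymal genes; integrins and laminins; matrix proteases; cadherins and protocadherins; gastric markers; intestinal markers; cholesterol synthesis; fatty acid and lipid synthesis; the IGF system; interferon-stimulated genes; antigen presentation; NF-kB targets and cytokines; hypoxia and glycolysis; endoplasmic reticulum stress; NRF2 targets; TGF-beta response; YAP targets; WNT targets; growth factor receptors and MAPK feedback; apoptosis regulators; cancer-testis antigens; ribosomal proteins; oxidative phosphorylation; metallothioneins; and markers of fibroblasts, leukocytes and endothelium as cell types foreign to the line. Each list was tested with camera (preset correlation 0.01, two-sided), adjusted over the 35 lists. Members were counted as changed over all genes tested and adjusted over the list alone. An estimated correlation, fry and rank-based camera were the alternatives.

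The steps were tested on simulated arrays of 19775 genes with the group sizes of this comparison and 200 changed genes in each of 20 runs. The spread of each gene was drawn from limma's own fitted model, alike in both groups. Over the runs the median number of calls was 181 and the median number of false calls was 10. On the real arrays the control pair differed more than the knockout pair, so these runs do not give the rate of false gene calls there. Of genes changed by 1, 2 and 3 on the log2 scale, 66.2%, 93.4% and 97.9% were recovered. A simulated list shifted by 0.3 was called in 20 of 20 runs, with 0 calls of unshifted lists, and a run with no change made at most 2 gene calls. Genes were simulated independently, so the simulated lists held no correlation between members. The estimated correlation of the real cholesterol synthesis list was 0.13, for example. These runs therefore do not give the rate of false list calls on the real arrays.

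Fold changes were also followed along the chromosomes, in windows of 50 consecutive genes with a mean above 4.75, the median of all probe sets. Neighbouring windows overlapped and shared most of their genes. Window medians were set against 1000 shuffles of the gene order. The alternatives tried were a filter on dim genes, a trended and robust variance model, the mean of a gene's probe sets, all probe sets tested separately, centring of each array on its median, quantile normalization, the replicate number as a block, a stricter adjusted p of 0.01, a test against a minimum fold of 1.5 (limma treat), and leaving out each array in turn. Cyclic loess normalization and a test without the genes of the chromosome 2 stretches were added after seeing the data.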

Results

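PRMT6 is a protein arginine methyltransferase that places an asymmetric dimethyl mark on arginine 2 of histone H3. The series set out to measure how its loss changes gene expression in NUGC3, an established human gastric cancer cell line. RMA log2 expression was compared between 2 arrays of PRMT6 knockout cells and 2 arrays of PRMT6 wild-type control cells. The 2 knockout arrays correlated at r = 0.998 across genes and 1 gene differed at least 2-fold between them, while the 2 control arrays correlated at r = 0.995 and 17 genes differed at least 2-fold. Between a knockout and a control array, 160 to 222 genes differed by that much. Control replicate 1 correlated with each knockout array at r = 0.995, about as closely as with control replicate 2, while control replicate 2 correlated with them at r = 0.992. Genes are not independent replicates, so these correlations only describe the arrays.

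The targeted gene was lower in both knockout arrays. PRMT6, measured by its only probe set, read 7.66 in each control array and 6.87 and 6.91 in knockout replicates 1 and 2, which is a log2 fold change of -0.77 (SE 0.073), or 1.70-fold lower. Its limma adjusted p of 0.0502 lay just above the threshold over all genes, and it was 0.0022 when adjusted over the list of arginine methyltransferases alone. An edit that shifts the reading frame need not remove the transcript, and the place of the probe set relative to the edit was not determined here, so this value checks the labels only in part.

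Knockout and control differed in 94 of 19775 genes, of which 71 (75.5%) rose and 23 fell in the knockout (limma, adjusted p under 0.05, n = 2 arrays per group). The share that rose was 63.6% after quantile and after cyclic loess normalization. At least 2-fold changes were called for 84 of these genes, 66 higher and 18 lower. At an unadjusted p under 0.05 there were 1210 higher and 1153 lower genes. The groups did not overlap in 43.3% of all genes, against 33.3% by chance. None of the 94 calls passed when any one array was left out, where the smallest adjusted p was 0.121, although all 94 kept their direction.

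The largest measured rise was in DMRT1, a transcription factor of testis development, which went from 3.37 ± 0.22 in control to 8.48 ± 0.097 in knockout cells (SD, n = 2 each), a log2 fold change of 5.11 (SE 0.13, adjusted p = 0.0086). Its control values lay close to the lower quartile of all probe sets on those arrays (3.22 and 3.29) and were not shown to be above background, so the exact fold and its rank are uncertain, as for other genes this dim in control. TENM2, a teneurin of the cell surface with a role in synaptic adhesion, rose by 4.14 (SE 0.14), from 4.39 to 8.53. CCND2, the G1 cyclin D2, rose by 3.39 on its brightest probe set, and its other probe sets gave 1.66, 0.34 and 0.05. LRRC55, an auxiliary subunit of a potassium channel, rose by 3.33, and LY75, an endocytic receptor known from dendritic cells, by 2.96. The cancer-testis antigens PAGE1 and SPANXB1 rose by 2.81 and 2.65. The secreted matrix-associated proteins CTHRC1 and SMOC2 rose by 2.58 and 2.50, the latter on 1 of 2 probe sets (the other gave -0.05). The pseudogene transcript ABCA17P rose by 3.45, NHSL2 by 3.12 and TSNARE1 by 2.40; the second probe set of NHSL2 gave -0.13 and the others of TSNARE1 gave 0.29 and 0.03. Of the 66 genes called at least 2-fold higher, 28 (42.4%) had a control mean below 4.75, the median of all probe sets, as did 35.3% of all genes tested.

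The largest measured fall was in ARMCX6, from 7.05 to 3.95 (log2 fold change -3.10, SE 0.079, adjusted p = 0.0086), while its dimmer second probe set gave 0.01. SETBP1, which encodes a SET-binding nuclear protein, changed by -2.73, with -1.73 on its second probe set. MMP1, the interstitial collagenase, changed by -2.16 (SE 0.072). HMMR, a hyaluronan-binding protein of the mitotic spindle, changed by -2.11 on both of its probe sets. The interferon-inducible genes IFI27 and IFI6 changed by -1.97 and -1.70. TGFBI, a matrix protein induced by TGF-beta, changed by -1.54, the gastric annexin ANXA10 by -1.39 and KITLG, the ligand of the KIT receptor, by -1.31. COX7B2, OR7E19P and the long noncoding RNA WAKMAR2 changed by -1.84, -1.69 and -1.48. The knockout means of SETBP1, COX7B2 and OR7E19P, at 2.67, 2.96 and 3.45, lay near or below the lower quartile of all probe sets on those arrays (3.22 and 3.21) and were not shown to be above background, so their exact folds and the order of the falls are uncertain. All 24 genes with the largest changes had knockout values on one side of both control values, as the rule for naming them required.

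**Figure D1:**
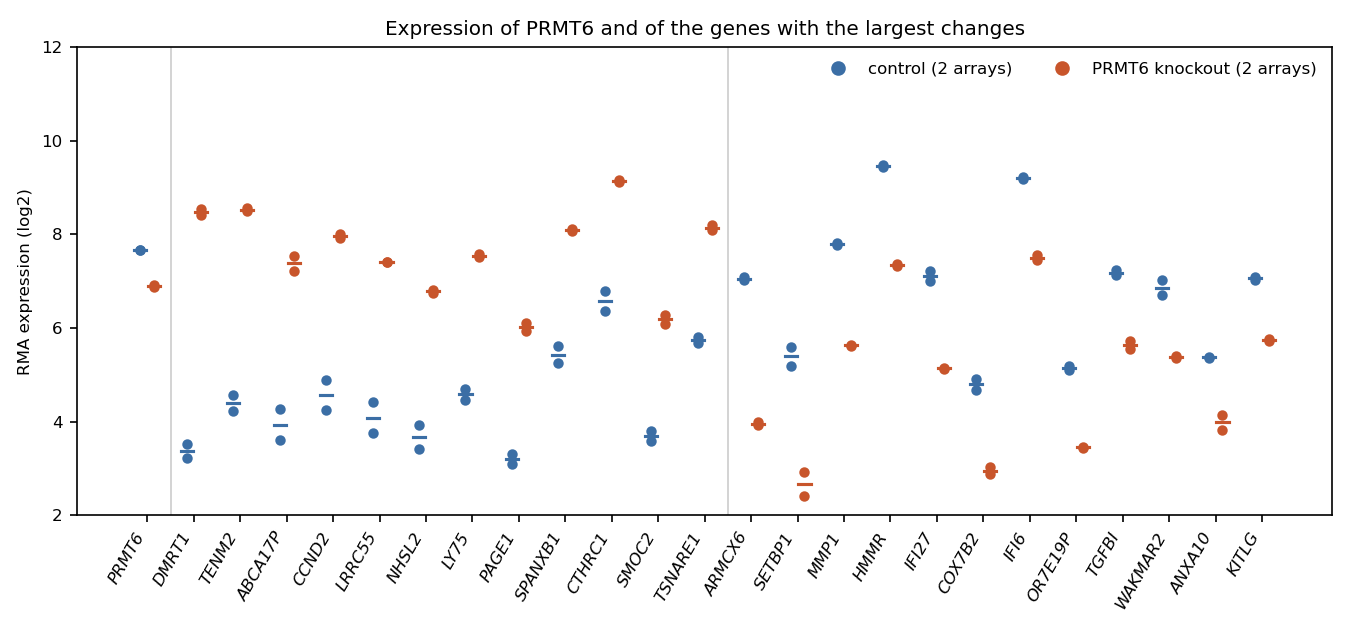
RMA log2 expression (vertical axis) of PRMT6, of the 12 genes with the largest rises and of the 12 with the largest falls; each point is 1 array (blue, control; orange, PRMT6 knockout) and each bar the mean of 2 arrays. DMRT1 goes from 3.37 to 8.48 and ARMCX6 from 7.05 to 3.95, whereas PRMT6 goes from 7.66 to 6.89.

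Of the genes fixed by name, SCD and IGFBP5 rose. SCD, the stearoyl-CoA desaturase, went from 9.29 to 10.42 (log2 fold change 1.13, SE 0.080, adjusted p = 0.0267), and its other probe sets gave 0.75 to 0.94. When all probe sets were tested, no probe set of SCD passed (smallest adjusted p = 0.0618). IGFBP5, an IGF-binding protein, rose by 1.34 (SE 0.075, adjusted p = 0.0189), with 0.93 to 1.67 over its 6 probe sets, of which 3 passed when all probe sets were tested. PCDH7, a protocadherin, was not called, with a log2 fold change of 0.31 (SE 0.21, adjusted p = 0.626) and overlapping groups; its dimmer probe sets gave 0.88, 0.45, 0.37 and -0.02, and none of them passed when all probe sets were tested. SCD, IGFBP5 and PCDH7 were recalled from the study itself and are not independent of these samples. The cell cycle inhibitors CDKN1A, CDKN1B and CDKN2A had log2 fold changes of 0.34, 0.13 and 0.0012 (adjusted p = 0.243, 0.572 and 0.999); that of CDKN2A was -0.0061 after quantile and -0.015 after cyclic loess normalization, and its dimmer probe sets gave 0.33 and 0.50. THBS1, the secreted angiogenesis inhibitor thrombospondin 1, gave 0.54 (SE 0.15, adjusted p = 0.282) on its brightest probe set. Its other probe sets gave 1.20, 1.08, 0.77, 0.72, 0.66 and -0.07, of which the first passed when all probe sets were tested (adjusted p = 0.0409). These inhibitors and THBS1 make up the 4 measured genes of the list reported elsewhere as repressed by PRMT6, of which 0 were changed over all genes and 2, CDKN1A and THBS1, were higher adjusted over the list alone. The list's median was 0.23 (camera adjusted p = 0.0913).

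The cholesterol synthesis list was shifted upwards by camera with the preset correlation (adjusted p = 9.26e-17), a call that was lost with an estimated correlation (adjusted p = 0.818) and by fry (adjusted p = 0.0776). All 19 measured members had positive log2 fold changes, with a median of 0.51. Over all genes, 2 members rose, HMGCS1 by 1.1 (SE 0.087, adjusted p = 0.0349) and the sterol C4 oxidase MSMO1 by 0.90 (SE 0.072, adjusted p = 0.0365); 15 were higher adjusted over the list alone. HMGCS1 makes the precursor of mevalonate. SQLE, the squalene epoxidase, and IDI1, the isopentenyl diphosphate isomerase, gave 0.71 and 0.64 without passing over all genes (adjusted p = 0.0595 and 0.0685). In 18 of the 19 both knockout values lay above both control values.

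The list of fatty acid and lipid synthesis was shifted upwards as well, with 16 of 23 members positive and a median of 0.18 (camera adjusted p = 0.0180; adjusted p = 0.818 with an estimated correlation). SCD was its only changed member, over all genes and adjusted over the list alone; FASN, ACSL4 and ACSS2 gave 0.43, 0.35 and 0.34 without passing. The shift was not called without control replicate 2 (median 0.16, adjusted p = 0.272), with the mean of all probe sets of a gene (0.11, adjusted p = 0.112) or with rank-based camera (adjusted p = 0.105). These were the only lists called of the 35. With an estimated correlation, and by fry, 0 lists were called, against 14 at an unadjusted camera p under 0.05.

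**Figure D2:**
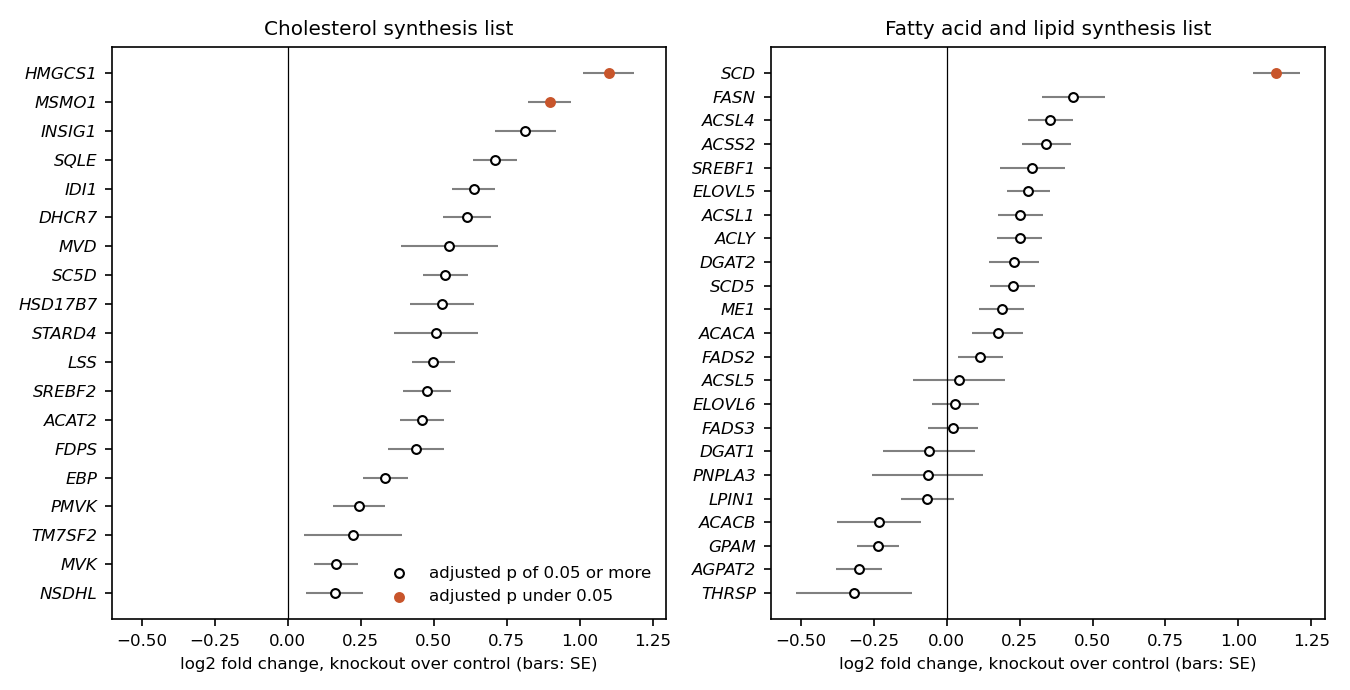
Log2 fold change of knockout over control (horizontal axis, points, with the SE as bars) of the measured genes of the cholesterol synthesis list (left, 19 genes) and of the fatty acid and lipid synthesis list (right, 23 genes). Filled points have an adjusted p under 0.05 over all genes: HMGCS1 (1.1) and MSMO1 (0.90) on the left and SCD (1.13) on the right.

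Interferon and cytokine genes moved in both directions. Among 33 interferon-stimulated genes, 3 fell (IFI27, IFI6 and OAS1, the last by -1.18) and 0 rose; adjusted over the list alone, 11 were lower and 8 higher, among them MX2 at -1.02, OASL at 0.85 and IFIT2 at 0.72. OASL and IFIT2 were chosen after their values were seen. The list as a whole was not shifted (median -0.15, camera adjusted p = 0.123). Of 31 NF-kB targets and cytokines, the chemokines CCL2 and CCL5 rose by 1.77 and 1.04 and IL1B, the cytokine interleukin 1 beta, changed by -1.06 (adjusted p = 0.0355); 10 members were changed adjusted over the list alone, 5 in each direction, and the list was not shifted (adjusted p = 0.914). CXCL5, a neutrophil chemokine, gave -0.77 (adjusted p = 0.0529). IL1B lies in a stretch of chromosome 2 whose genes were lower in the knockout. Antigen presentation (20 genes) held 0 changed genes and 3 higher adjusted over the list alone, including CD74, the invariant chain, at 0.86 (list adjusted p = 0.0972).

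Several signalling lists held single changed genes without a shift of the list. In the IGF system (17 genes) IGFBP5 rose and 5 genes were higher adjusted over the list alone, with IGFBP2 at 1.04, IGFBP7 at 0.42 and IGFBP4 at 0.42 (list adjusted p = 0.0604). In the WNT target list (21 genes) the intestinal stem cell factor ASCL2 rose by 1.58, and SP5 and ZNRF3 were higher adjusted over the list alone, at 0.67 and 0.64 (list adjusted p = 0.415). In the TGF-beta list (22 genes) TGFBI fell and 6 genes passed adjusted over the list alone, 3 in each direction, including the pseudoreceptor BAMBI at 1.3, FST at -0.56 and the receptor TGFBR2 at -0.70. That list's median was 0.068 and its mean -0.0013 (adjusted p = 0.721). Growth factor receptors and MAPK feedback genes (31) held 0 changed genes and 6 adjusted over the list alone, 3 in each direction (list adjusted p = 0.362). The feedback inhibitor SPRY2 gave 1.01 and the immediate early gene EGR1 0.70, while the feedback inhibitors DUSP6 and SPRED2 gave -0.38 and -0.42, the latter in a chromosome 2 stretch that was lower in the knockout. YAP targets (21) had 0 changed genes over all genes or adjusted over the list alone, with AXL at 0.43 (list adjusted p = 0.0604).

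Among stress lists, hypoxia and glycolysis (29 genes) held 0 changed genes and 3 adjusted over the list alone: the prolyl hydroxylase EGLN3 at 0.95, the glucose transporter SLC2A3 at 1.01 and hexokinase HK2 at -0.60. The median of that list was -0.044 and its mean 0.018 (adjusted p = 0.721), and HK2 lies in a stretch of chromosome 2 that was lower in the knockout. HK2 is near an end of that stretch, and its nearest neighbours above the median level, SEMA4F and LOC105374809, gave -0.29 and 0.27. NRF2 targets (22) had 0 changed genes, 4 higher and 1 lower adjusted over the list alone, with TXNRD1 at 0.49 and HMOX1 at 0.47 (list adjusted p = 0.123). Endoplasmic reticulum stress (30 genes, adjusted p = 0.192) and metallothioneins (7 genes, adjusted p = 0.922) held 0 changed genes on either count. Genes induced by DNA damage (21) held 0 changed genes on either count, with MDM2 at 0.44 (list adjusted p = 0.123). Apoptosis regulators (24) had 0 changed genes and 2 adjusted over the list alone, CFLAR at -0.51 and PMAIP1 at 0.45 (list adjusted p = 0.784).

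HMMR was the only gene of the proliferation lists changed over all genes. In the G2/M list (30 genes) 26 members were positive and the median was 0.054, while the mean was -0.023 (adjusted p = 0.252). BUB1, a kinase of the spindle checkpoint, was lower adjusted over the list alone, at -0.42. Replication and G1/S (28 genes) held 0 changed genes on either count, with RRM2 at -0.35 and MCM6 at -0.33 (list adjusted p = 0.306). BUB1, RRM2 and MCM6 all lie in stretches of chromosome 2 that were lower in the knockout. Oxidative phosphorylation (25 genes, 20 negative, adjusted p = 0.123) held 1 gene lower adjusted over the list alone, COX5B at -0.51, which lies in one of these stretches as well. Ribosomal protein genes (25) held 0 changed genes on either count (adjusted p = 0.733).

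Chromatin and lineage lists were not shifted. Of 9 arginine methyltransferases, PRMT6 was the only one lower adjusted over the list alone, and PRMT5 gave -0.19 (list median 0.016, mean -0.075, adjusted p = 0.721). HOX genes (28 measured) and H3K4 methyltransferase complexes (17) held 0 changed genes on either count (adjusted p = 0.802 and 0.252). The HOX median was 0.011 and the mean -0.026, with HOXB8 at -1.21 (adjusted p = 0.113) and HOXB3 at 0.41. Epithelial adhesion and keratin genes (27) and mesenchymal genes (25) held 0 changed genes on either count (adjusted p = 0.585 and 0.123), with KRT7 at 0.49, E-cadherin (CDH1) at -0.35 and COL3A1 at -0.32. Cadherins and protocadherins (27, adjusted p = 0.319), integrins and laminins (16, adjusted p = 0.802) and intestinal markers (21, adjusted p = 0.123) likewise held 0. Among matrix proteases (23) MMP1 fell and 5 genes passed adjusted over the list alone, with PLAU at 0.57, MMP9 at 0.56, TIMP3 at -0.43 and ADAM17 at -0.40 (list adjusted p = 0.733). ADAM17, named after its value was seen, lies in a stretch of chromosome 2 that was lower in the knockout. Of 27 gastric markers ANXA10 fell, and adjusted over the list alone MUC1 was higher at 0.64 and GATA6 lower at -0.70 (list adjusted p = 0.123). Of 19 cancer-testis antigens PAGE1 rose, while the list's median was -0.068 and its mean 0.064 (adjusted p = 0.478).

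Lists of markers of cell types foreign to a carcinoma line had low median levels and held 0 changed genes over all genes. The median control level was 4.23 for fibroblast, 4.23 for leukocyte and 3.96 for endothelial markers, and their median log2 fold changes were -0.15, -0.12 and -0.11 (camera adjusted p = 0.284, 0.710 and 0.123). One leukocyte marker, CORO1A, was bright in these cells (8.70 in control) and higher adjusted over the list alone, at 0.52.

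Along the genome, genes of chromosome 2 were lower together. Of 2329 overlapping windows of 50 neighbouring genes above the median level, 56 had a median log2 fold change below that of all 1000 shuffles of the gene order. All 56 lay on chromosome 2, and 0 windows lay above the shuffles. Neighbouring windows share most of their genes, so the 56 are not separate regions. The 56 windows formed 3 stretches, each from the first gene of its first window to the last gene of its last. The ends of a stretch can therefore hold genes that were not lower, and they do not mark the ends of a lowered segment. From USP39 to SPC25 the median over 210 genes was -0.30 (95% bootstrap interval -0.35 to -0.26), and 172 of them were negative. From CHAC2 to SH2D6 it was -0.16 over 135 genes, and from FAM110C to ITSN2 it was -0.14 over 70 genes. The stretches were chosen for their low medians, so these medians and the interval only describe them. Of the 657 genes tested in the stretches, 3 passed over all genes. IL1B and PAX8-AS1 fell (the latter was named after its value was seen), and LY75 rose. LY75 lies near one end of its stretch, where its nearest neighbours above the median level, MARCHF7 and RBMS1, gave 0.05 and -0.03. No gene of the cholesterol synthesis list lies in them. INSIG2, a relative of the list member INSIG1, does lie in the stretch from USP39 to SPC25. It gave -0.71 (limma adjusted p = 0.0638) and was named after its value was seen. The absence of list members therefore does not separate the shift of that list from these stretches, and a link was not tested.

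**Figure D3:**
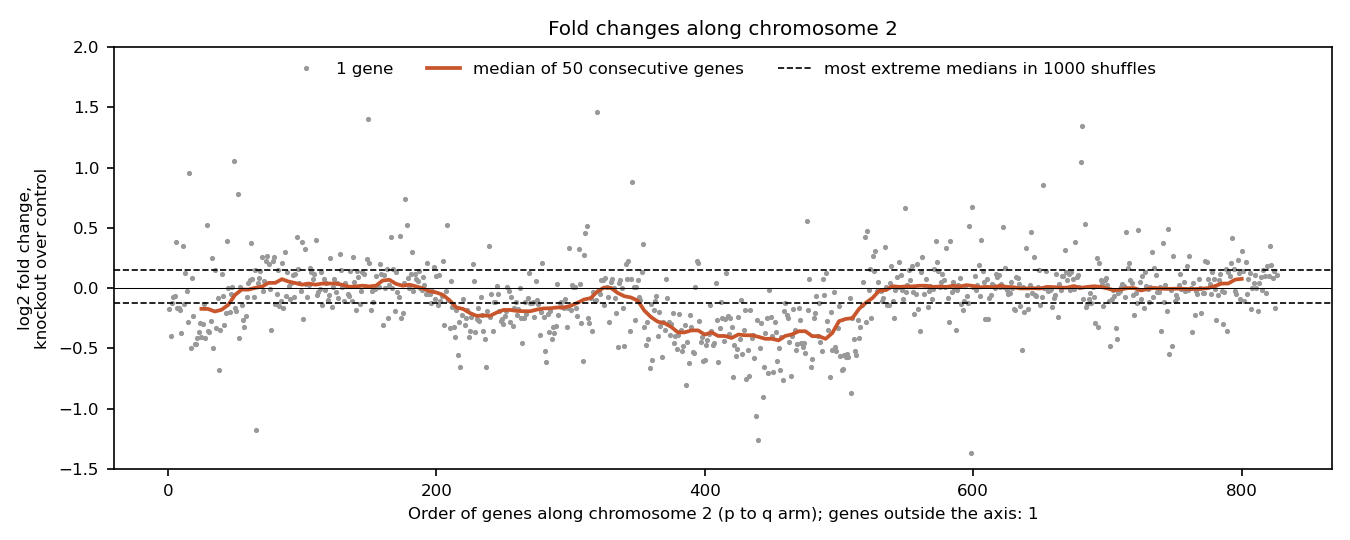
Log2 fold change of knockout over control (vertical axis) of genes above the median level in their order along chromosome 2 (horizontal axis); grey points are single genes, the orange line is the median of 50 consecutive genes and the dashed lines are the most extreme window medians in 1000 shuffles of gene order. The window medians fall as low as -0.43 in the stretch from USP39 to SPC25.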

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

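Among the 13522 probe sets with several gene symbols or none, which took no part in the comparison of genes, 10 were changed when all probe sets were tested (limma, adjusted p under 0.05), 5 higher and 5 lower in the knockout. They were flagged because they carry a signal outside the genes reported. They are not named here, and no explanation was tested.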

How the results depend on the processing

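Cyclic loess normalization and the test without the chromosome 2 stretches were chosen after seeing the data; the other alternatives were planned. The count of 94 changed genes became 309 with only bright genes (61.2% higher), 835 with a trended and robust variance (58.0% higher), 164 with centred arrays, 195 after quantile normalization (63.6% higher), 231 after cyclic loess (63.6% higher), 2 at an adjusted p under 0.01, and 0 when any one array was left out (range 0 to 0). It stayed within 1.5 times with the mean of all probe sets (138), all probe sets (81) and without the chromosome 2 stretches (90). All 94 genes were called again with the trended variance, the centred arrays and cyclic loess, 93 after quantile normalization, but 75 with the mean of all probe sets. Every gene tested again kept its direction in every setting for which this was counted, which leaves out the test of all probe sets. Except with the mean of all probe sets, this was close to fixed in advance, since the genes were called on the same arrays and probe sets. The count of 84 genes changed at least 2-fold became 162 with the trended variance, 26 with treat and 0 with the replicate block or any array left out (range 0 to 0). Leaving out an array leaves 1 array in a group, assumed to vary like the other group; at an unadjusted p under 0.05 these fits gave 4892 and 2518 genes without control replicates 1 and 2 and 999 and 954 without knockout replicates 1 and 2. The replicate numbers did not pair the arrays (the deviations of same-numbered arrays correlated at -0.0665); with the replicate block limma called 0 genes, with 1942 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0823, and 2 lists.

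PRMT6 passed the threshold with bright genes only (-0.77, adjusted p = 0.0197), the trended variance (-0.77, 0.00208), the mean of probe sets (-0.77, 0.0324), centred arrays (-0.76, 0.0382), quantile normalization (-0.83, 0.0348) and cyclic loess (-0.81, 0.0309), and missed it elsewhere, up to an adjusted p of 0.860. The 2 shifted lists became 5 with bright genes only, 5 with the mean of probe sets, 4 after quantile normalization, 0 with an estimated correlation, 0 with fry, 1 with rank-based camera, and 1 to 6 with one array left out. Cholesterol synthesis (median 0.51) was lost with an estimated correlation (adjusted p = 0.818) and with fry (0.0776). With 4 arrays, camera with an estimated correlation could hardly call any list. Fatty acid and lipid synthesis was lost with the mean of probe sets (0.11, adjusted p = 0.112), and at 0.18 with an estimated correlation (0.818), fry (0.199) and rank-based camera (0.105); with one array left out it ranged from 0.12 to 0.20. CDKN2A changed sign after quantile normalization (-0.0061) and cyclic loess (-0.015) and ranged from -0.041 to 0.043 with one array left out. For 102 genes followed, 899 values with all arrays gave 721 with the same call, 71 weaker, 105 stronger and 2 reversed; 408 with one array left out gave 218, 188, 0 and 2. The cause of these changes was not tested, apart from the loss of an array. Signal close to background limits the folds of dim genes, and the probe set chosen decides several (CCND2, ARMCX6, SMOC2, NHSL2, TSNARE1, SOX30 and CT75 among them).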

Other observations

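The tests of clonal differences and those of a single deviating array were chosen after the results were seen, as were the genes named in the next paragraph.

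Outside the lists, genes that rose in the knockout included SOX30, a transcription factor of spermatogenesis, by 1.61, TDRD5, a tudor-domain protein of the germline, by 1.67, the testis transcript CT75 by 1.73 and the actin-like gene ACTL8 by 1.20 (adjusted p = 0.0466, 0.0162, 0.0236 and 0.0204). The second probe sets of SOX30 and CT75 gave -0.24 and 0.38. No enrichment of germline genes was tested, and the fixed list of cancer-testis antigens was not shifted (camera adjusted p = 0.478). Others were the endothelin receptor EDNRB at 2.12, the interleukin receptors IL17RB and IL7R at 1.95 and 1.17 and the ephrin receptor EPHB1 at 1.70 (0.50 on its second probe set). FKBP5, a chaperone partner known as a glucocorticoid-induced gene, rose by 1.64, the calcium-binding inflammatory protein S100A8 by 1.44 and the mitochondrial transhydrogenase NNT by 1.82. TXNIP, an inhibitor of glucose uptake, the calcium-binding protein CALB1 and the adhesion protein AMIGO2 changed by -1.23, -1.10 and -1.12.

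A first pattern is the set of genes called at least 2-fold higher. Around the 66 genes of this set, the 5 nearest bright genes on each side had a median log2 fold change of 0.028 (95% bootstrap interval 0.0092 to 0.042). A gain of the chromosome segment around each gene was thus excluded as a cause shared by the set. Being a median, this value does not exclude gains around some of the 66 genes, or gains too short to reach these neighbours. Cross-hybridisation of a single probe set stays open: over 39 of these genes with more than 1 probe set the second brightest gave a median of 0.72 (0.35 to 1.04), and in 17 genes it exceeded 0.5 times the brightest. Differences between clones unrelated to PRMT6 stay open too, because 1 gene differed at least 2-fold between the knockout arrays, as it would if both held 1 clone, and the labels do not say how many clones there were. A derepression of these genes upon loss of PRMT6 is a hypothesis that cannot be told apart from a clone effect here.

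A second pattern is that the control arrays differed more from each other than the knockout arrays did, with SDs of the difference of 0.25 and 0.157, a ratio of 1.59. After cyclic loess of the already normalized values the ratio was 1.47 (1.45 to 1.5). An intensity-dependent difference that this step can remove was therefore not the whole cause. One that arose earlier, in the authors' normalization, was not tested. Noise of dim probe sets was not the whole cause either, since the ratio was 1.78 (1.75 to 1.82) among bright genes. The intervals resample genes within the same 2 arrays per group, so they do not measure how the ratio would vary over other arrays. A control culture with more mixed cells than a cloned knockout, or a deviation of control replicate 2 alone, may lie behind the ratio, and neither was tested.

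The last pattern is the lower expression of 3 stretches of chromosome 2. Shared fold changes of neighbours are what a loss within these stretches in the knockout cells, or a gain in the control cells, would give. Either could affect only part of the population. In all, 56 overlapping windows of 50 bright genes lay beyond every shuffle, and none outside chromosome 2. A single deviating array, which leaves the pairs without it near 0, was excluded for the stretch from USP39 to SPC25. Its weakest median was -0.303 over the 4 pairs of a knockout and a control array and cyclic loess. From CHAC2 to SH2D6 (weakest -0.149, -0.19 to -0.11) it was excluded only under a looser limit, a part of that stretch's own median. Both limits were set after the values were seen. For the stretch from FAM110C to ITSN2 a single deviating array stays open under the looser limit. The weakest median there was -0.109 (-0.23 to -0.024), over genes chosen for their low values. Cyclic loess could not test the authors' normalization, because it was run on values already normalized by them. RMA as described above takes no account of the position of a gene. On the other chromosomes 0 windows lay beyond the shuffles, with medians from -0.076 to 0.107. The lowest window medians of the 3 stretches were -0.19, -0.23 and -0.43. These values argue against the authors' normalization as the cause of the 3 stretches. Whether such a change came with the cloning or with the loss of PRMT6 cannot be tested with these arrays, and a DNA copy number measurement was not used here.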
